A study of Mus musculus with 8 samples.

How the data were processed

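Messenger RNA was measured in 8 libraries of mouse kidney mononuclear phagocytes on a C57BL/6J background. Per the labels, 4 libraries were macrophages and 4 were monocytes. Each subtype came from 4 genotype samples. The C5 arm held a wild type and a C5 knockout, in which LyzMcre, a Cre recombinase expressed from the lysozyme locus of myeloid cells, acts on a floxed C5 gene. The C5AR1 arm held a wild type and a knockout of the C5a receptor gene made in the same way. Per the series design text, kidneys were taken 14 days after folic acid, a chemical that injures the tubule, and each group was pooled. That text names the C5 arm, and the day for the C5AR1 arm is not given in the sources used here. Each of the 8 groups held 1 library. The macrophage and monocyte libraries of 1 arm and genotype are together called a pool, giving 4 pools. Whether they came from the same animals, and how many animals there were, is not given in the sources used here.

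Per the labels' protocols, libraries were made from poly(A) RNA with a SENSE kit, in which starter and stopper primers hybridise along the RNA, and were amplified by PCR without mention of molecular identifiers. Reads of 1 molecule copied by PCR therefore count several times, and all counting intervals and floors given here cover counting error only. Per the submitters' processing notes, Trim Galore 0.6.5, STAR, featureCounts 2.0.2, R 4.1.0, edgeR 3.34 and the mm10 genome are named, without roles. The STAR version, the annotation, the strand setting and the treatment of reads with several positions are not given in the sources used here. Genes that share sequence with a close copy, such as Lyz1 and Lyz2, are therefore uncertain at the level of the single gene.

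The deposited count table holds raw read counts for 24421 gene symbols in the 8 libraries, and it was the source of all main results. The deposited normalised signal holds the same counts divided by 1 constant per library, for 16095 genes; every gene left out had a total of at most 41 counts. Both statements were tested on the values, and the scaling method the authors used is not given in the sources used here. No per-sample column was left unused. Mitochondrially encoded genes were not analysed here, so 1 of the 31 gene lists was not tested.

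From the raw counts, log2 fold changes were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a filter on low counts with a minimum count of 10 that kept 13406 genes, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Macrophages and monocytes were compared with pool as a block, leaving 3 residual degrees of freedom. The block rests on the shared arm and genotype. After removing subtype means, the 2 libraries of the C5_WT, C5_KO, C5AR1_WT and C5AR1_KO pools correlated across genes at -0.164, -0.0306, 0.324 and 0.0572, so the values did not pair the libraries in every pool. In the C5AR1_WT and C5AR1_KO pools the macrophage library correlated best with its own monocyte library (the highest other value was 0.196 and 0.0398), and in the C5 arm it did not. Knockout and wild type were compared over both arms with terms for arm and subtype, leaving 4 residual degrees of freedom, and the difference in knockout effect between subtypes with pool as a block, leaving 2. Each group has 1 library, so these p-values measure the spread between these libraries and not between animals.

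Within an arm each subtype had 1 library per group, so knockout and wild type were compared per subtype with no replicate check and no test. As an alternative, each arm was fitted alone by edgeR over both subtypes, with 1 residual degree of freedom. Values there are CPM after TMM scaling, with log2 differences at a prior count of 2. They are described by a rule of size, an absolute log2 difference of at least 1 in the same direction in both subtypes. The wild-type pools of the 2 arms were compared by the same rule as background. Similarity between arms is a correlation across genes, which are not independent replicates, so no p-value is given.

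Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusting over the lists of a comparison. Within an arm, the median of a list was placed among 10000 random lists of the same size matched on mean expression in 10 bins. Intervals for single counts are exact Poisson intervals at 95%, and a count of 0 is set against a floor of 3 counts per library. Gene positions are from the GENCODE annotation of mm10 (GRCm38).

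Genes are named by a rule. For the tests across libraries it takes, among genes past the threshold with a mean CPM of at least 10 and 1 direction in all 4 pairs, the 12 with the largest rise and the 12 with the largest fall. With fewer than 5 knockout calls it takes the 10 highest and 10 lowest by the smallest absolute difference over the 4 pairs, as values. Within an arm it takes the 10 per direction with the largest smaller difference, at a mean CPM of at least 10 over the arm. The C5 pathway, cytokine and lysozyme genes, and the 4 members of each list with the largest fitted change, are added. The groups, tests, lists, naming rule and main alternatives were chosen before the data were examined.

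The tests were tested on simulated counts, 5 draws of 13406 genes with 200 changed, using each gene's own fitted dispersion and, separately, the trended one. The changed genes were drawn from those with a mean CPM of at least 10, so recovery below that CPM was not measured. For macrophages against monocytes the tests recovered 71.6% and 75.2% of 8-fold changes, 48.4% and 53.6% of 4-fold and 8.8% and 7.2% of 2-fold changes. For knockout against wild type they recovered 62.4% and 74% of 8-fold, 42.4% and 52% of 4-fold and 1.2% and 8% of 2-fold changes. For the difference between subtypes they recovered 38% and 32% of 8-fold, 12% and 10.4% of 4-fold and 0.4% and 0% of 2-fold changes. Unchanged genes made up 13.1% and 3.39% of the calls between macrophages and monocytes, 7.34% and 5.63% of those for the knockout and 44.8% and 20.3% of those for the difference, against a nominal 5%, while 3.4% to 4.1% of unchanged genes had an unadjusted p under 0.05. Where a gene's own dispersion varies as much as fitted here, the calls therefore hold more unchanged genes than the threshold states.

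Alternatives were other scaling, filters and prior counts, DESeq2 1.42.0, limma voom, limma on the log2 of the deposited normalised values with 1 added, other covariates, summed pools, single arms and subtypes, and leaving out each pool or library. Those added after the data were seen were leaving out the 3 libraries that detect the fewest genes (with no pool block or arm term), a mean CPM of at least 50, a newer edgeR method of estimating the quasi-likelihood dispersion, and the list tests without a pool or library. Leaving out the 3 libraries left C5_KO_Mac, C5AR1_KO_Mac, C5AR1_WT_Mac, C5_WT_Mono and C5AR1_WT_Mono. The knockout was then measured in macrophages alone, with C5AR1_WT_Mac as the only wild type. Macrophages were compared with monocytes that were all wild type, so subtype was mixed with genotype.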

Results

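The data were raw counts of 8 libraries, 1 for each combination of arm, genotype and subtype. The series title places the work on C5a receptor activity in macrophages and the production of interleukin 1 beta in sterile inflammation. Groups are written as arm, WT for wild type or KO for knockout, and Mac for macrophage or Mono for monocyte. In the C5 arm total counts were 28317330 in C5_WT_Mac, 54913237 in C5_WT_Mono, 62342873 in C5_KO_Mac and 31232943 in C5_KO_Mono. In the C5AR1 arm they were 66901147 in C5AR1_WT_Mac, 50443114 in C5AR1_WT_Mono, 75415771 in C5AR1_KO_Mac and 18780921 in C5AR1_KO_Mono. In each library the gene with the most counts was Cd74, the invariant chain of MHC class II, at 3.12% to 6.27% of counts. Thinned to 18780921 counts, 3 libraries held fewer detected genes than the rest: C5_KO_Mono 11751, C5_WT_Mac 12086 and C5AR1_KO_Mono 12278, against 14290 to 16055 in the other 5. Each of the matched knockout and wild-type pairs except the C5AR1 macrophages contained 1 of these 3 libraries. A floor of 3 counts corresponded to 0.0416 CPM in the deepest library and 0.166 CPM in the shallowest.

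**Figure D1:**
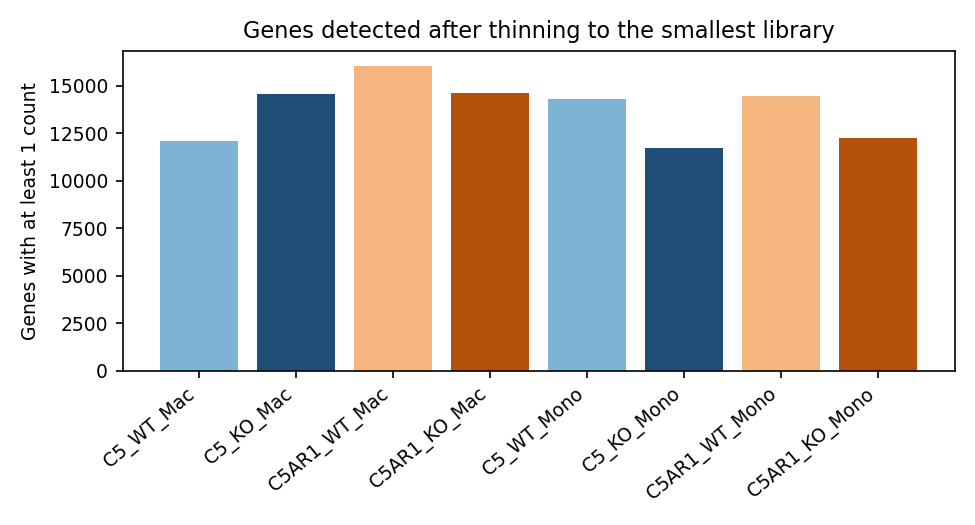
Number of genes with at least 1 count in each of the 8 libraries (1 library per bar, Mac macrophage, Mono monocyte, WT wild type, KO knockout) after thinning all libraries to 18780921 counts. C5_WT_Mac, C5_KO_Mono and C5AR1_KO_Mono lie at 12086, 11751 and 12278 genes, and the other 5 at 14290 or more.

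The targeted genes were examined first, as a check of the labels. C5ar1, which encodes the C5a receptor (chromosome 7, 16246743 to 16259540, minus strand), was 4.03-fold lower in C5AR1 knockout macrophages, at 70.01 CPM (95% Poisson interval 68.1 to 72.0) against 282 CPM (278 to 286). The library labelled C5AR1 knockout monocyte was not lower: it had 69.7 CPM (65.9 to 73.6), against 64.1 CPM (62.1 to 66.3) in its wild type. Monocytes of the C5 arm had 221 CPM in the wild type and 292 CPM in the knockout, so both monocyte libraries of the C5AR1 arm lay below them, and C5AR1_WT_Mono was the lowest of the 8. The count against its own wild type therefore goes against the knockout label, does not show the deletion, whose extent the labels do not give, or rests on a low wild-type library. C5AR1 knockout monocyte means the library labelled so wherever it is named. Hc, the mouse gene of complement C5 (chromosome 2, 34983331 to 35061438), had 0 counts in 7 of the 8 libraries, wild types of the C5 arm included, and 53 counts in C5AR1_WT_Mac, so it checked no label. C5ar2, the second C5a receptor (chromosome 7, 16234585 to 16244154, on the same strand and 2588 bases from C5ar1), was higher in both C5AR1 knockout libraries, at 213 against 39.0 CPM in macrophages and 35.9 against 5.24 CPM in monocytes, or 5.47-fold and 6.85-fold. In the C5 arm C5ar2 was 28.7 against 39.7 CPM in macrophages and 22.8 against 5.26 CPM in monocytes.

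**Figure D2:**
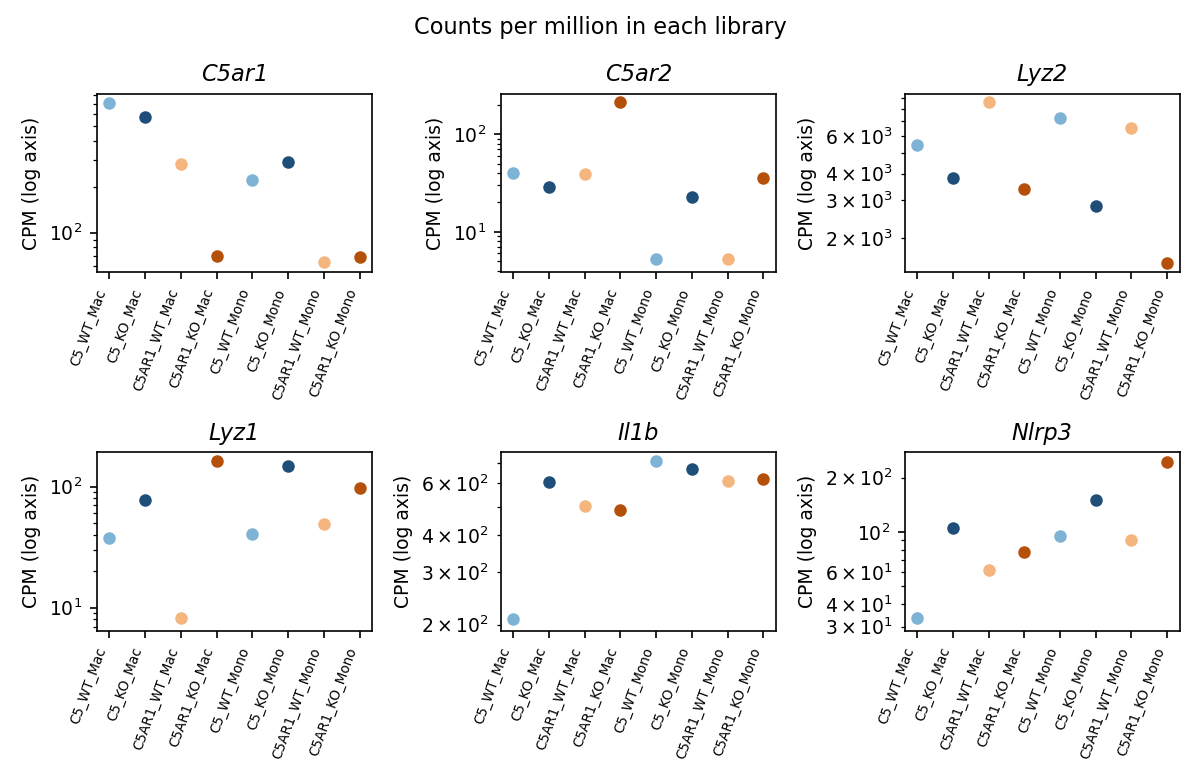
CPM of C5ar1, C5ar2, Lyz2, Lyz1, Il1b and Nlrp3 in each of the 8 libraries, on log axes; bars are 95% Poisson intervals of counting error and are mostly smaller than the points. C5ar1 stands at 282 CPM in C5AR1_WT_Mac and 70.01 CPM in C5AR1_KO_Mac, and Lyz2 is lower in the knockout library of each pair.

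Macrophages were compared with monocytes within the 4 pools. The genes that rose most in macrophages included Ccl8 and Ccl7, chemokines that attract monocytes, at log2 fold changes of 6.94 ± 0.78 (SE, 4 pools; adjusted p 0.00502, edgeR) and 5.30 ± 0.72 (0.0108), and Vcam1, an adhesion molecule, at 6.43 ± 1.09 (0.0238). Igf1, a growth factor, rose by 5.72 ± 1.14 (0.0434), the matrix genes Col14a1 and Cyr61 by 6.43 ± 0.89 (0.0113) and 5.46 ± 0.67 (0.00743), and Mmp13, a collagenase, by 5.18 ± 0.86 (0.0228). Lower in macrophages were Cd209a, a C-type lectin of monocyte-derived dendritic cells, at -6.25 ± 0.47 (0.00201), Ace, angiotensin-converting enzyme and a marker of non-classical monocytes, at -6.10 ± 0.77 (0.00835), and S100a8, an alarmin of monocytes and neutrophils, at -4.84 ± 0.82 (0.0237). Cd209a had 12.02, 1.45, 25.5 and 6.95 CPM in the macrophage libraries of the C5 wild type, C5 knockout, C5AR1 wild type and C5AR1 knockout pools, and 467, 321, 1336 and 580 CPM in the monocyte libraries.

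The other named genes that rose were Ptprm, Stard13, B3galnt1, Olfml3 and Itga8, an integrin subunit, with log2 fold changes of 5.61 to 8.53 and adjusted p of 0.0108 to 0.0366 (edgeR). Those that fell were Serpinb10, Ptgir, the prostacyclin receptor, Cd177, Mmp9, a gelatinase, Ltb4r1, a leukotriene B4 receptor, Htr7, Cd7, Zbtb46, a transcription factor of dendritic cells, and Pi16, at -7.22 to -4.77 with adjusted p of 0.0220 to 0.0492. Ptprm had 0 counts in C5_KO_Mono and Ptgir 0 counts in C5_WT_Mac. Stard13 and B3galnt1 in C5_KO_Mono (0.0638 CPM) and Serpinb10 and Cd177 in C5_WT_Mac (0.0729 and 0.0364 CPM) lay below 3 counts. The size of change of all of these depends on the prior count. Vcam1 differed by 4.17 and 4.65 in the C5 and C5AR1 wild-type pools and by 9.96 and 7.72 in the knockout pools. For Igf1 these were 4.11, 3.31, 8.74 and 7.15, but for Stard13 7.57, 7.65, 7.91 and 5.07. Both knockout monocyte libraries were of low gene detection. Leaving out 1 pool ended the call of 8 of the 24 named genes without C5_WT, 10 without C5_KO, 12 without C5AR1_WT and 17 without C5AR1_KO. Ccl8, Ccl7, Col14a1, Cyr61 and Cd209a stayed past the threshold in all 4 cases. None of C5ar1 (1.21 ± 0.35, adjusted p 0.149), C5ar2 (2.23 ± 0.54, 0.0865), Il1b (-0.62 ± 0.30, 0.445), Nlrp3 (-1.05 ± 0.29, 0.122), Tgfb1 (-1.13 ± 0.27, 0.0814), Lyz2 (0.39 ± 0.30, 0.661), Il18 (0.09 ± 0.64, 0.970), Tnf (0.44 ± 0.33, 0.653), Il6 (1.57 ± 2.95, 0.878) or Il10 (0.26 ± 2.83, 0.981) passed the threshold.

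**Figure D3:**
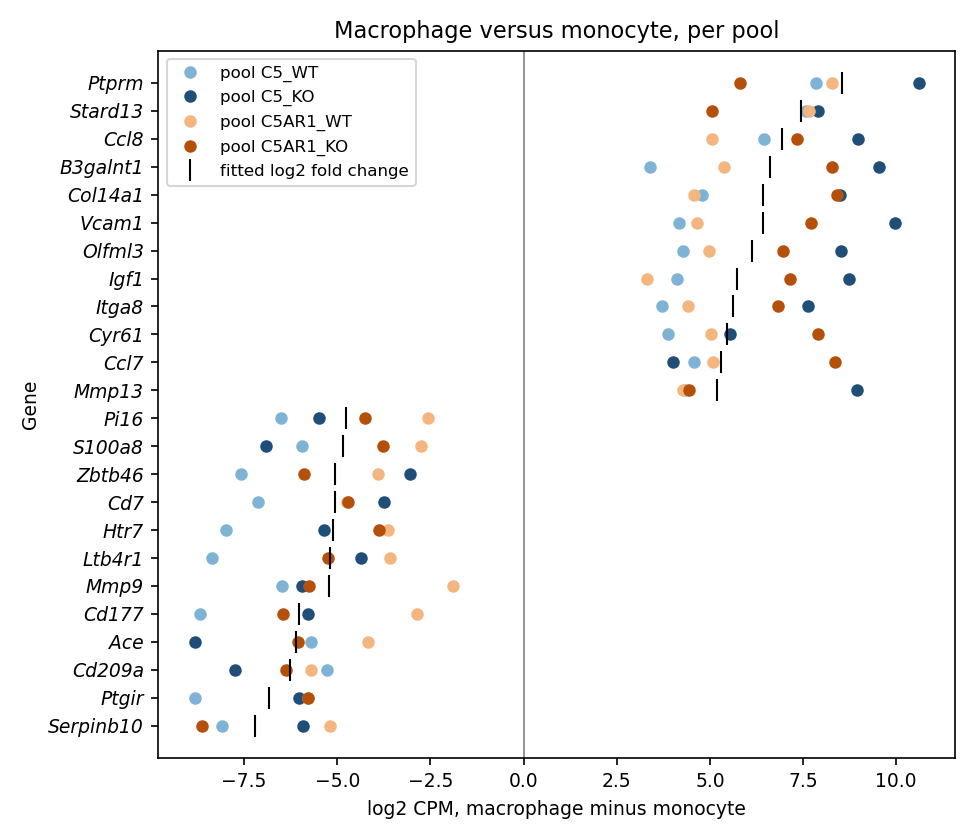
Log2 CPM of the macrophage minus the monocyte library in each of the 4 pools (1 point per pool) for the 24 named genes, with the log2 fold change fitted over the pools as a black tick. The 12 genes that rose lie to the right of 0 in all 4 pools and the 12 that fell to the left.

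Among macrophage identity markers, 18 of 27 rose and 0 fell (22 rose adjusted over the list alone). Ms4a7 rose by 4.80 ± 0.34 (adjusted p 0.00191, edgeR), Tmem119 by 4.60 ± 0.82 (0.0276) and C1qa, a subunit of the first complement component, by 4.07 ± 0.43 (0.00385). The list had an adjusted p of 1.71e-16 by camera and an adjusted p of 0.249 with an estimated correlation. Among complement genes 5 of 21 rose and 0 fell, with 7 higher and 3 lower adjusted over the list alone, and C4b rose by 4.25 ± 0.58 (0.0108, edgeR). Its adjusted p was 0.00325 by camera and 0.346 with an estimated correlation. Of 26 genes of lysosomes and phagocytosis 6 rose (15 adjusted over the list alone). Among them were Mertk, a receptor for apoptotic cells, at 3.24 ± 0.39 (0.00734, edgeR) and Ctsb, a lysosomal protease, at 1.57 ± 0.23 (0.0136). The adjusted p of this list was 0.000193 by camera and 0.333 with an estimated correlation.

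Among classical monocyte markers 13 of 22 fell in macrophages and 0 rose (18 fell adjusted over the list alone), with Plac8 at -4.24 ± 0.38 (adjusted p 0.00212, edgeR) and Hp, haptoglobin, at -4.47 ± 0.65 (0.0131). Camera gave an adjusted p of 3.86e-18, and it was 0.249 with an estimated correlation. Of 17 non-classical monocyte markers 5 fell and 1 rose (7 and 2 adjusted over the list alone), with Adgre4 at -3.07 ± 0.21 (0.00191, edgeR) and Nr4a1, a nuclear receptor needed by these monocytes, at -2.97 ± 0.26 (0.00212). Its adjusted p was 2.6e-05 by camera and 0.316 with an estimated correlation.

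Markers of other cell types differed between the subtypes as well. Of 14 neutrophil markers 5 fell in macrophages, Cd177 and Mmp9 among them (8 adjusted over the list alone). Cd177 is also on the list of classical monocyte markers and Mmp9 on that of alternative activation genes, so these falls are not particular to neutrophils. The neutrophil list's adjusted p was 1.34e-08 by camera and 0.249 with an estimated correlation. Of 19 dendritic cell markers 5 fell (6 lower and 1 higher adjusted over the list alone), such as Flt3, a growth factor receptor, at -3.75 ± 0.38 (adjusted p 0.00347, edgeR). Camera gave an adjusted p of 0.00325, and it was 0.316 with an estimated correlation. Of 12 NK cell markers 2 fell (2 adjusted over the list alone), Klrd1 at -4.14 ± 0.70 (0.0237, edgeR). Its adjusted p was 0.000193 by camera and 0.249 with an estimated correlation.

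Kidney tubule markers were higher in macrophages for 21 of 23 genes, of which 2 rose (3 adjusted over the list alone). The adjusted p was 0.000541 by camera, 0.333 with an estimated correlation, and 0.202 by camera without the 3 libraries of low gene detection. All 13 B cell markers were higher and 0 passed the threshold (0 adjusted over the list alone). The list's adjusted p was 0.025 by camera and 0.510 with an estimated correlation. By camera it was 0.281 without C5_WT, 0.121 without C5_KO and 0.143 without the 3 libraries. Of 6 erythroid and platelet genes 1 rose (1 adjusted over the list alone), Pf4, a platelet chemokine, by 4.56 ± 0.78 (adjusted p 0.0238, edgeR). Pf4 is also a member of the chemokine list, so its rise alone does not show platelet transcripts. For the erythroid and platelet list camera gave an adjusted p of 0.0373, and it was 0.58004 with an estimated correlation. By camera it was 0.121 without C5_KO, 0.0700 without C5AR1_WT and 0.0923 without C5AR1_KO. Of 28 cell cycle genes 24 were higher and 0 passed the threshold (0 adjusted over the list alone), with an adjusted p of 0.00325 by camera and 0.339 with an estimated correlation.

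Of 22 NF-kB response genes 3 fell (8 lower and 2 higher adjusted over the list alone), with an adjusted p of 0.00101 by camera and 0.249 with an estimated correlation. Of 21 glycolysis genes 2 fell and 1 rose (7 and 1 adjusted over the list alone). Those that fell were Slc16a3, a lactate transporter, at -2.28 ± 0.28 (adjusted p 0.0074, edgeR) and Pfkp, a phosphofructokinase, at -2.23 ± 0.28 (0.00791). Its adjusted p was 0.000138 by camera and 0.336 with an estimated correlation. Of 21 cholesterol synthesis genes 3 fell (5 adjusted over the list alone). The list's adjusted p was 0.000454 by camera and 0.282 with an estimated correlation. Of 28 immediate early and dissociation stress genes 2 fell (4 adjusted over the list alone), Nr4a1 and Dusp2. Camera gave an adjusted p of 0.0266, and it was 0.336 with an estimated correlation, and by camera 0.144 without C5AR1_KO and 0.575 without the 3 libraries. The test of direction within a list, fry, called 6 of the 16 lists that camera called: NF-kB response, both monocyte classes, macrophage identity, lysosome and NK cells.

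Of the lists that camera did not call, chemokines had 7 genes that rose and 1 that fell of 22 (adjusted p 0.267), profibrotic genes 5 and 3 of 23 (0.267), and alternative activation genes 4 and 5 of 26 (0.0687). The inflammasome and IL-1 list had 1 gene that rose and 1 that fell of 23, the decoy receptor Il1r2 at -2.37 ± 0.46 (0.0382 by edgeR), with a camera adjusted p of 0.0577. The camera adjusted p was 0.0511 for nuclear oxidative phosphorylation genes, 0.0513 for endothelial markers, 0.267 for fibroblast and matrix genes and 0.596 for mitochondrial dynamics genes. It was 0.749 for T cell markers and both MHC classes, 0.898 for interferon-stimulated genes, 0.902 for ribosomal proteins and 0.989 for X and Y dosage genes. For interferon-stimulated and X and Y dosage genes the median and the test differed in sign. By camera, fibroblast and matrix genes were called without C5_WT (0.00972), alternative activation genes without C5AR1_WT (0.0455) and endothelial markers without C5AR1_KO (0.00546). Without the 3 libraries of low gene detection, interferon-stimulated (0.00901) and ribosomal genes (0.00901) were called lower in macrophages, and endothelial (0.0131), fibroblast (0.0345) and profibrotic genes (0.0474) higher. The monocyte libraries left, C5_WT_Mono and C5AR1_WT_Mono, are both wild type, while the macrophages include C5_KO_Mac and C5AR1_KO_Mac. With no pool or genotype term, subtype is mixed with genotype in that fit.

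By edgeR 401 of 13406 genes passed the threshold, 170 higher and 231 lower in macrophages; 1740 genes had an unadjusted p under 0.05, where 670.3 are expected by chance. The count was 219 without C5_KO, 139 without C5AR1_WT and 163 without C5AR1_KO. It was 678 without the 3 libraries of low gene detection (293 of them among the 401), where subtype is mixed with genotype. It was 887 by limma voom, 1073 by the newer edgeR dispersion method and 1790 by DESeq2. Of the DESeq2 calls 1046 were higher and 744 lower in macrophages, or 58.4% higher. Most calls were higher also by edgeR in the wild-type pools alone (160 of 294) and at a mean CPM of at least 50 (335 of 649).

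Knockout was compared with wild type over both arms and subtypes. Lyz2, the lysozyme gene of myeloid cells (chromosome 10, 117277331 to 117282321), from whose locus LyzMcre is expressed, was lower in the knockout library of each pair. It was lower by 1.43-fold and 2.57-fold in C5 macrophages and monocytes and 2.55-fold and 4.28-fold in the C5AR1 ones, with a fitted log2 fold change of -1.34 ± 0.32 (SE, 8 libraries; unadjusted p 0.00292, adjusted p 0.993, edgeR). Lyz1 (chromosome 10, 117287797 to 117292868) was higher in each, by 2.06-fold, 3.64-fold, 19.8-fold and 1.97-fold in the same order, at 1.94 ± 0.53 (adjusted p 0.993). Hspa1b, an inducible heat shock protein 70, was higher in each knockout library, by 1.63, 2.13, 1.03 and 1.09 on the log2 scale in the same order (1.45 ± 0.29, unadjusted p 0.00102, adjusted p 0.993). Neither these nor any other gene passed the threshold of this test.

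By edgeR 0 genes passed, with 371 at an unadjusted p under 0.05 and 670.3 expected by chance; limma voom, limma on the normalised values and the newer edgeR method also gave 0. DESeq2 gave 15 genes, Fkbp5 and Hspa1b higher and 13 lower, Lyz2, Map7 and Slc5a12 among them. Fkbp5 was chosen after its values were seen. Of 8780 genes with a mean CPM of at least 10, 1190 had 1 direction in all 4 pairs, or 13.6%, and 9 of these differed by at least 1 on the log2 scale in each pair. Independent pairs would give 12.5%, but the other 7 patterns of direction over the 4 pairs took 9.09% to 17.9% of genes, with 3 to 52 genes of that size, 52 where the arms went opposite ways. Named by the smallest of the 4 differences, the higher genes were Kcnj2, a potassium channel, Rfx2, Myom1, Saal1, Ipo7, Uba6, Zfp346 and Cdca7 besides Hspa1b and Lyz1, with fitted log2 fold changes of 1.05 to 2.82. The lower ones were Map7, Slc5a12, a lactate transporter of the proximal tubule, Dcun1d4, Mal2, Arg1, arginase 1, Galnt3, Capn5, Acaa1b, Def8 and Mcemp1, at -4.80 to -1.38. Without the 3 libraries of low gene detection the fitted values of Cdca7, Uba6 and Lyz1 went from 1.84, 1.05 and 1.94 to -0.08, 0.27 and 3.90, and those of Map7, Slc5a12, Mal2 and Galnt3 from -4.80, -3.66, -3.42 and -2.62 to -1.47, -0.58, -0.05 and -0.45. Of the 20 genes named by this rule, all but Lyz1 had fitted values closer to 0 without these libraries. With them left out, the fit rests on C5_KO_Mac and C5AR1_KO_Mac against C5AR1_WT_Mac alone, and so mixes arm with genotype. Arg1 was 3.90 against 14.9 CPM in C5 macrophages, 3.89 against 127 CPM in C5 monocytes, 10.1 against 21.7 CPM in C5AR1 macrophages and 0.775 against 24.1 CPM in C5AR1 monocytes.

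Il1b, which encodes interleukin 1 beta (chromosome 2, 129364570 to 129371139), was 607 CPM (601 to 613) in C5 knockout macrophages and 208 CPM (203 to 214) in their wild type, a 2.91-fold difference. That wild-type library, C5_WT_Mac, had the lowest Il1b of the 8, with 488 to 711 CPM in the other 7, and was 1 of the 3 of low gene detection; C5AR1_WT_Mac lay 1.27 above it on the log2 scale. In the other 3 pairs Il1b was 673 against 711 CPM in C5 monocytes, 488 against 503 CPM in C5AR1 macrophages and 619 against 609 CPM in C5AR1 monocytes. The fitted change was 0.31 ± 0.31 (adjusted p 0.993, edgeR). Nlrp3, the sensor of the inflammasome that matures interleukin 1 beta, was higher in each knockout library, by 3.14-fold, 1.57-fold, 1.27-fold and 2.68-fold in C5 macrophages and monocytes and C5AR1 macrophages and monocytes (1.03 ± 0.27, unadjusted p 0.00504, adjusted p 0.993). Its lowest value too was in C5_WT_Mac, at 33.7 CPM against 61.3 to 242 CPM in the other 7. The fitted changes were -0.42 ± 0.38 for C5ar1, 1.86 ± 0.57 for C5ar2, -0.40 ± 0.59 for Il18, 0.40 ± 0.34 for Tnf, -4.48 ± 2.54 for Il6, 1.76 ± 2.33 for Il10 and 0.36 ± 0.27 for Tgfb1, each with an adjusted p of 0.993. Without the 3 libraries of low gene detection the values of C5ar1, Il18 and Il6 had the opposite sign, at 0.19, 0.24 and 2.17. Il6 had 0 counts in C5_KO_Mono and 1 in C5AR1_KO_Mono, and Il10 had 0 in C5_WT_Mac and 1 in C5AR1_KO_Mono. These are the 3 libraries of low gene detection, so the sizes of both fitted changes are uncertain.

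Of 30 lists camera called 4. Interferon-stimulated genes were lower in knockouts for 27 of 30 members (adjusted p 0.00147, and an adjusted p of 0.940 with an estimated correlation), with 0 past the threshold alone; Isg15, a ubiquitin-like protein induced by interferon, was at -1.41 ± 0.75 and Ifit1 at -1.75 ± 0.81. Its medians were -1.07 and -1.79 in C5 macrophages and monocytes, at percentile 0 of random lists, but 0.40 and 0.15 in the C5AR1 arm, and -1.08 and -1.14 in the C5AR1 wild type minus the C5 wild type. Isg15 had 91.6 and 128 CPM in the C5 wild type and 12.2 to 36.0 CPM in the other 6 libraries. Immediate early and dissociation stress genes were higher for 23 of 28 (0.000559, and an adjusted p of 0.940 with an estimated correlation), with Hspa1a at 1.05 ± 0.36; 1 rose adjusted over the list alone, Hspa1b. Its medians were 0.54 (percentile 100) and 0.15 (81.3) in C5 macrophages and monocytes, 0.07 (28.9) and 0.30 (71.6) in the C5AR1 ones, and 0.30 and 0.16 (99.96 in both) in the C5AR1 wild type minus the C5 wild type. Nuclear genes of oxidative phosphorylation were lower for 46 of 50 (0.00387, and an adjusted p of 0.940 with an estimated correlation), with Ndufa9, a subunit of complex I, at -0.73 ± 0.34, and medians of 0.29 (percentile 99.9), -0.56 (0), -0.28 (0) and -0.61 (0) in C5 macrophages and monocytes and C5AR1 macrophages and monocytes. Cholesterol synthesis genes were lower for 19 of 21 (0.0133, and an adjusted p of 0.940 with an estimated correlation), with Sqle, squalene epoxidase, at -1.51 ± 0.46. Its medians were -0.22 (percentile 15.5), -1.10 (0.39), -0.22 (1.27) and -0.22 (40.3) in the same order, and the knockout library of the second pair, C5_KO_Mono, was 1 of the 3 of low gene detection. The other 26 lists had camera adjusted p of 0.0738 to 0.868, kidney tubule markers 0.0858 with 19 of 23 members lower. The median and the test differed in sign for macrophage identity, lysosome, T cell, endothelial, profibrotic and X and Y dosage genes, none of them called.

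Single libraries decided several of these list calls. Without C5_WT_Mac, C5_KO_Mono or C5_KO_Mac the adjusted p by camera was 0.423, 0.0883 and 0.359 for the interferon-stimulated genes and 0.236, 0.207 and 0.0999 for cholesterol synthesis, and without C5AR1_KO_Mac it was 0.0975 for cholesterol synthesis and for oxidative phosphorylation. Kidney tubule markers, lower in the knockouts, were called without C5_WT_Mac (0.00417), C5_WT_Mono (0.0163), C5_KO_Mono (0.0437) or C5_KO_Mac (0.000945). These and the further calls without 1 library use the preset correlation. Over all libraries each list had an adjusted p of 0.940 by camera with an estimated correlation. Classical monocyte markers were called lower without C5_WT_Mono (0.0163), C5_KO_Mono (0.0335), C5AR1_WT_Mono (0.00183) or C5AR1_KO_Mono (0.0107). Other lists were called without 1 library: B cell markers lower without C5_WT_Mono (0.038), ribosomal genes lower (0.0251) and neutrophil markers higher (0.0158) without C5AR1_WT_Mac, and alternative activation genes lower without C5AR1_WT_Mono (0.0254). The number of lists called was 7 without C5_WT_Mono and 2 without C5AR1_KO_Mac. Without the 3 libraries of low gene detection the knockout term set C5_KO_Mac and C5AR1_KO_Mac against C5AR1_WT_Mac alone, so only directions are given. Whether the list calls above hold without these libraries cannot be told from that fit. It placed kidney tubule, neutrophil, T cell, dendritic cell and classical monocyte markers lower in these knockout macrophages, and ribosomal and cell cycle genes higher. Ribosomal and cell cycle genes had been lower for most members in the full comparison, with 32 of 36 and 18 of 28 genes lower, and neutrophil markers higher for 11 of 14. T cell markers, with 8 of 17 higher there, turned by the test as well, and the direction of the interferon-stimulated genes turned to higher without the 3 libraries.

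**Figure D4:**
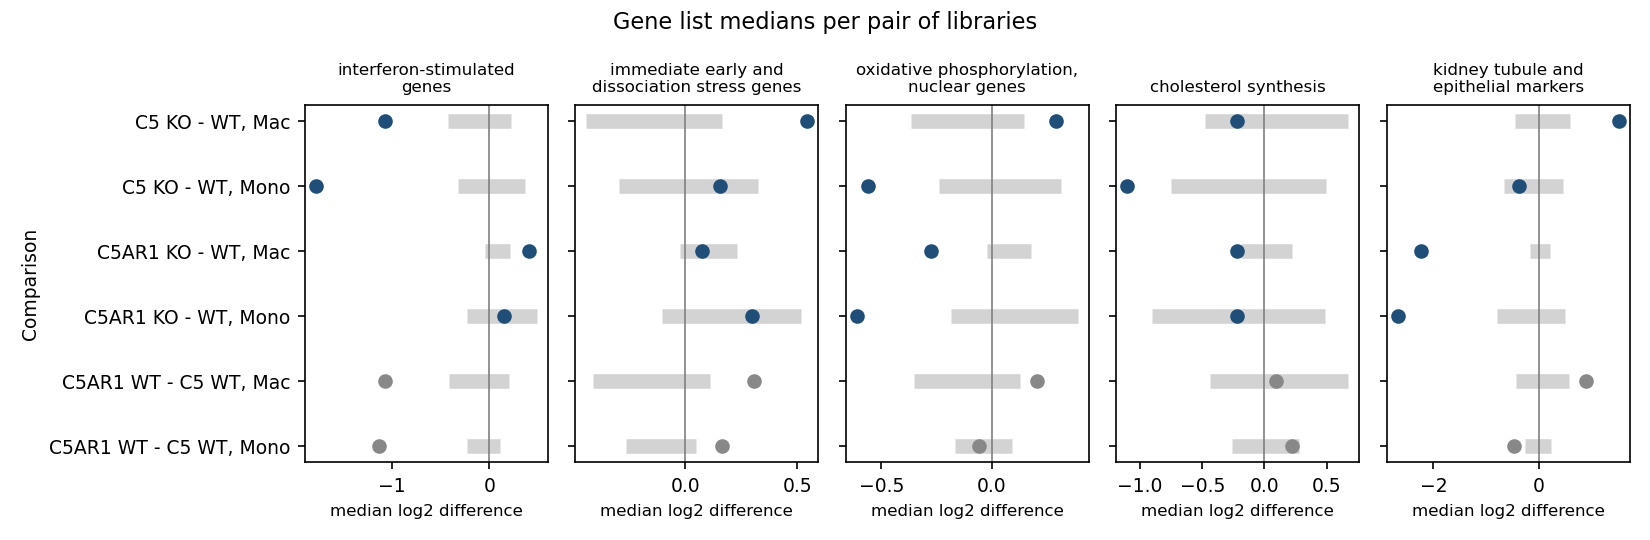
Median log2 difference of 5 gene lists in each pair of libraries (points; blue, knockout minus wild type within an arm; grey, C5AR1 wild type minus C5 wild type), against the central 95% of 10000 random lists matched on size and mean expression (grey bands). Each panel has its own axis. Interferon-stimulated genes lie at -1.07 and -1.79 in the C5 arm and at -1.08 and -1.14 between the wild types.

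Whether the knockout effect differed between macrophages and monocytes was tested within pools. Col14a1, a collagen, and Vcam1 had the smallest p in this test. Col14a1 was lower in both knockout monocyte libraries, at 0.638 against 17.1 CPM in the C5 arm and 0.940 against 10.02 CPM in the C5AR1 arm, and 243 against 470 CPM and 336 against 241 CPM in macrophages. Both knockout monocyte libraries and C5_WT_Mac, the 3 of low gene detection, enter this contrast with the same sign, for each gene and list given here. Without them no knockout monocyte library is left and the difference has no value. With the filter on low counts the difference of Col14a1 was 3.84 ± 0.42 (SE, 8 libraries) at an adjusted p of 0.467, and that of Vcam1 4.43 ± 0.74 at 0.849 (edgeR). Classical monocyte (18 of 22 members lower, adjusted p 0.000412 by camera), non-classical monocyte (14 of 17, 0.000423) and neutrophil markers (11 of 14, 0.000423) had lower knockout effects in macrophages than in monocytes, with Chil3, a chitinase-like protein, at -2.34 ± 0.40 and Ly6c2 at -2.81 ± 0.84. Adjusted over the list alone 1 classical monocyte gene fell. For each list the adjusted p was 0.979 with an estimated correlation. C5ar1 had a difference of -1.43 ± 0.46 (unadjusted p 0.0165, adjusted p 0.849, edgeR), and Il1b 0.78 ± 0.54 (0.849). By edgeR 0 genes passed, with 669 at an unadjusted p under 0.05 and 670.3 expected; limma voom, limma on the normalised values and the newer edgeR method gave 0 and DESeq2 534. Without the filter on low counts 2 genes passed, Col14a1 (adjusted p 0.0289) and Vcam1 (0.0419), and without C5AR1_KO_Mono 1, Cd38 (0.0393); Col14a1, Vcam1 and Cd38 were chosen here after their values were seen.

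Within the C5 arm the knockout was set beside its wild type in each subtype, as values of 1 library each. Egf, epidermal growth factor, which the distal tubule makes, was 641 against 1.68 CPM in macrophages and 246 against 13.02 CPM in monocytes, and Casr, the calcium-sensing receptor, 40.5 against 0.474 and 60.5 against 3.01 CPM. Slc22a6, an organic anion transporter of the proximal tubule, was 53.6 against 3.17 and 15.3 against 0.106 CPM. Isg15 was lower, at 12.2 against 91.6 CPM in macrophages and 15.5 against 128 CPM in monocytes, as were Vcan, the matrix proteoglycan versican of classical monocytes, at 0.0659 against 1.09 and 4.56 against 37.3 CPM, and Phf11a, at 9.87 against 74.8 and 0.159 against 62.6 CPM. Otud7b, Egln3, a prolyl hydroxylase induced by hypoxia, and Tbx21, a transcription factor of NK and T cells, had 0 counts in C5_WT_Mac and were at least 62.8-fold, 29.8-fold and 11.9-fold higher in C5 knockout macrophages, against 3 counts in that library. The other named genes were Plxnb1, Rtkn, Adgrf5 and Nid1, a basement membrane protein, on the higher side and Fancf, Pole, the catalytic subunit of DNA polymerase epsilon, Foxm1, a mitotic transcription factor, Creg2, Mgat3, Hibch and Chml on the lower side. In C5_WT_Mac Plxnb1 and Rtkn had 1 count and Adgrf5 and Nid1 2 counts. In C5_KO_Mono Fancf had 0 counts, Pole, Foxm1, Mgat3 and Hibch 1 and Chml 2. All but Creg2 thus lay under 3 counts in a library of low gene detection, which leaves the size of their change uncertain.

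In all, 907 genes were higher and 758 lower in both subtypes, while 2308 differed by at least 1 in opposite directions in the 2 subtypes. At a mean CPM of at least 10 these were 664 genes in the same direction and 475 in opposite ones. The differences in macrophages and monocytes had a Pearson correlation of -0.142 across the 13406 genes and 0.0417 across those of at least 10 CPM. The wild type of the macrophage pair, C5_WT_Mac, and the knockout of the monocyte pair, C5_KO_Mono, were of low gene detection. Opposite directions can therefore not be read as opposite effects in the 2 subtypes. Kidney tubule markers had a median of 1.51 in macrophages (percentile 100 of random lists) and -0.38 in monocytes (12.7), neutrophil markers 0.17 (58.3) and 2.10 (100), complement genes -0.18 (21.98) and -1.95 (0), and MHC class II genes 0.77 (100) and -1.05 (0). T cell markers lay at percentiles 99.8 and 100, with Lck, a kinase of T cells, at 20.5 against 12.2 CPM in macrophages and 50.1 against 2.80 CPM in monocytes.

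Within the C5AR1 arm, the named genes lower in the knockout included several that the renal tubule expresses. Cyp4b1, a cytochrome P450, was 13.5 against 138 CPM in macrophages and 0.277 against 55.6 CPM in monocytes. Alpl, alkaline phosphatase, was 5.27 against 52.2 and 0.277 against 15.96 CPM, Slc17a1, a phosphate transporter, 4.03 against 36.6 and 0.277 against 6.49 CPM, and Cyp24a1, the vitamin D hydroxylase, 3.53 against 29.9 and 0.277 against 23.3 CPM. The values of 0.277 CPM rest on 5 counts in C5AR1_KO_Mono. Lck was 2.77 against 29.8 and 0.221 against 32.1 CPM. Ptprf, Ugt3a2, Ugt2b38, Cldn2, a tight junction protein of the proximal tubule, and Slc22a12, the urate transporter, were the other lower genes. Slc22a12 had 2 counts in C5AR1_KO_Mono, under the floor. Kidney tubule markers had medians of -2.23 and -2.67 (percentile 0 in both subtypes), and neutrophil markers -2.13 (0) and 0.43 (95.1). T cell markers lay at percentile 0 in both.

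C5ar2 headed the genes higher in both C5AR1 knockout libraries. It was followed by E2f8, a cell cycle transcription factor, at 11.5 against 2.71 CPM in macrophages and 21.1 against 6.35 CPM in monocytes, and Gm14023, D830031N03Rik, Bmpr2, a BMP receptor at 37.6 against 14.4 and 86.5 against 19.2 CPM, Kcnj2, BC048403, Ncapg2, Hirip3 and Zfp955a. By the rule 105 genes were higher and 1278 lower in both subtypes, and 433 went opposite ways. At a mean CPM of at least 10 the rule was met by 247, and 63 went opposite ways. The monocyte library of this knockout was among the 3 of low gene detection and had no counterpart.

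As background, the wild-type pools of the 2 arms differed by the same rule in 1205 genes, 962 higher and 243 lower in the C5AR1 wild type, and in 262 at a mean CPM of at least 10, against 664 in the C5 arm and 247 in the C5AR1 arm; 902 went opposite ways in the 2 subtypes, or 89 at that CPM. Egf was higher by 6.56 and 2.83 on the log2 scale in the macrophages and monocytes of the C5AR1 wild type than of the C5 wild type, and Isg15 differed by -1.99 and -2.36. Tubule markers had medians of 0.90 (percentile 99.8) and -0.47 (0.03), neutrophil markers 3.40 (99.99) and 1.10 (100), complement genes -0.03 (51.1) and -1.18 (0), and MHC class II genes 0.85 (100) and -0.0028 (82.6). T cell markers lay at percentiles 99.99 and 100, and X and Y dosage genes had medians of 7.55 and 8.81 (percentile 100 in both). The wild types thus differed in genes of the sex chromosomes as well, and are not a neutral background. Low gene detection also enters unequally, through C5_WT_Mac and C5_KO_Mono in the C5 arm, C5AR1_KO_Mono in the C5AR1 arm and C5_WT_Mac here. In the C5 arm the tubule, neutrophil, complement, MHC class II and T cell medians of both subtypes had the same signs as here, the MHC class II median of monocytes being near 0 here and -1.05 there; both differences are taken from the same C5 wild-type libraries.

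The C5 and C5AR1 knockout differences had a Pearson correlation across 13406 genes of -0.251 in macrophages and 0.208 in monocytes (Spearman -0.215 and 0.173), over genes, which are not independent replicates. The other 2 pairings of the same libraries gave -0.0883 and -0.133 in macrophages and 0.196 and 0.0171 in monocytes. Interferon-stimulated genes and tubule markers had opposite median signs in C5 and C5AR1 macrophages, at -1.07 and 0.40 and at 1.51 and -2.23, while Lyz2 and Nlrp3 had the same signs in both arms. At a mean CPM of at least 10 the monocyte value was 0.0858. Both knockout monocyte libraries were of low gene detection, so the monocyte correlation cannot be separated from it.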

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

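The tests of the lower sequencing depth, of abundant genes, of the summed lysozyme counts, of other myeloid lists, of the C5ar1 neighbours, of noise for C5ar2, the split counts for the knockout comparison and the splits within pools were chosen only after the result was seen.

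C5ar1, the gene targeted in the C5AR1 arm, stood out because its knockout change had opposite signs in the 2 subtypes. It was lower in both knockout macrophage libraries, with a mean log2 change of -1.17, and higher in both knockout monocyte libraries, with 0.26, a difference of -1.43. The edgeR test of that difference gave an unadjusted p of 0.0165 and an adjusted p of 0.849. In macrophages the change was -2.01 in the C5AR1 arm and -0.33 in the C5 arm, and in monocytes 0.12 and 0.40. The macrophage mean thus came mostly from the arm in which C5ar1 is targeted. Among 20 such checks, each with a chance of 12.5% were the pairs independent, 2.5 are expected by chance and 1 was seen.

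The first pattern is that C5_WT_Mac, C5_KO_Mono and C5AR1_KO_Mono detected fewer genes than the other 5 libraries. Lower depth is argued against, since at equal depth the highest of the 3 had 12278 genes and the lowest of the others 14290, and so is a large share of counts in few genes, since the top 10 genes took at most 10.3% in the 3 and up to 16.4% in the others. Fewer RNA molecules behind the reads stay open: the number of molecules per CPM was at most 0.338 in the 3 libraries and at least 0.703 in the others, but it is estimated from genes with 0 counts, so it restates the pattern and decides nothing. A biological cause was not tested, and no arm, genotype or subtype is common to all 3 libraries.

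The second pattern is that Lyz2 was lower and Lyz1 higher in the knockout library of all 4 pairs. The genes share 422 stretches of 31 bases, but a shift of reads between them is argued against as the whole cause, since their summed CPM in the knockouts was at most 70.6% of the wild type. A general fall of abundant myeloid transcripts is argued against in the C5AR1 arm, where Lyz2 lay at least 2.95 SD below the median of 41 lysosome and macrophage identity genes of at least 50 CPM, but cannot be told apart in the C5 arm, where the smaller gap was 0.746 SD, within the spread of those genes. The median test statistic of 27 genes within 5 Mb was at percentile 7.83 of random sets, which argues against a segment that changes many genes there and not against 1 that changes a few. The Cre insertion at the lysozyme locus, a biological explanation that follows the genotype, may account for the pattern and was not tested; the edgeR adjusted p of both genes was 0.993.

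The third pattern is that C5ar2 was higher in both C5AR1 knockout libraries. Shared reads are argued against, since the transcripts of C5ar1 and C5ar2 have 0 stretches of 31 bases in common, and a change of the whole neighbourhood is too, since 0 of 6 genes within 100 kb rose in both libraries. Noise between libraries cannot be told apart. As large a rise in both subtypes was seen in 26 genes between the wild-type pools and in 48 in the C5 arm. These were up to 0.547% of 8780 genes. Both comparisons take their macrophage difference from C5_WT_Mac, of low gene detection, and the C5AR1 macrophage pair holds no such library. The SD of macrophage differences was 1.76 between the wild-type pools, 1.77 in the C5 arm and 0.578 in the C5AR1 arm. This background is therefore wider than the spread of that pair. Ranked by its smaller rise over the subtypes, C5ar2 stood first in its arm. In C5AR1 macrophages 3 genes, C5ar2 included, rose as much. Transcription running on from the altered C5ar1 gene and a response to the loss of C5ar1 may each account for it, and neither was tested. In monocytes C5ar1 itself was not lower than in the wild type of that arm, and C5ar2 was also 4.33-fold higher in C5 knockout monocytes.

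For the 401 genes between macrophages and monocytes, 1 of 32 splits of the 8 libraries that could be fitted gave as many, the real one, and the highest other gave 0. The comparison is made within pools, and 8 of these splits put 1 library of each pool on either side, too few for a share under 0.05. For the knockout comparison the real count was 0, which each of the 33 splits reaches whatever its values, so the splits tested nothing there.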

How the results depend on the processing

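The settings without the 3 libraries of low gene detection, at a mean CPM of at least 50, with the newer edgeR dispersion method, and the list tests without a pool or library were chosen after the data were seen; the cause was not tested where none is given. For macrophages against monocytes the count of 401 became 1790 by DESeq2, 887 by limma voom and 1073 by the newer edgeR method. It became 649 at a mean CPM of at least 50, and 678 without the 3 libraries, where subtype is mixed with genotype. It became 100 in the knockout pools alone (fewer samples) and 139 to 364 without 1 pool. The knockout count of 0 became 15 by DESeq2. It became 37 in the C5 arm alone and 1 in the C5AR1 arm alone, with 1 residual degree of freedom and 1 pool per genotype. The difference between subtypes, 0, became 2 with no filter, 534 by DESeq2 and 0 to 1 without 1 library. By the rule of size, a mean CPM of at least 10 (fewer genes) gave 664, 247 and 262 genes for the C5 arm, the C5AR1 arm and the wild-type pools, a log2 difference of 0.58 gave 2880, 2176 and 2169, and 2 gave 639, 638 and 494. The monocyte similarity was 0.0858 at a mean CPM of at least 10. Lists called went from 16 to 0 with an estimated correlation and 6 by fry, from 4 to 0 and 0 for the knockout, with 8 without the 3 libraries and 2 to 7 without 1 library, and from 3 to 0 and 0 for the difference. The other settings kept their counts within 1.5-fold, and RLE scaling changed no call of a named gene. No call of a named gene reversed, and 78 calls of named macrophage genes were lost over all settings, 15 of 24 in the knockout pools alone. In the knockout comparison 713 values of named genes moved by less than the SD of that gene's 4 pair differences. This margin is wide and admits changes of sign. Without the 3 libraries, Kcnj2 went from 2.82 to 0.71 and C5ar1 from -0.42 to 0.19 within it. Another 11 values moved more, and 4 passed the threshold under DESeq2. No paired analysis was possible by replicate number because each group has 1 library and the groups share 1 number. The block used was the pool: without it 440 genes passed between macrophages and monocytes, and 3 of the 24 named genes, Ptgir, Mmp9 and S100a8, were not called.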

Other observations

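The genes of both paragraphs were chosen after their values were seen, and the single-arm fits were planned before. Genes of the Y chromosome separated the arms. Ddx3y, an RNA helicase gene on the Y, had 0.0494 to 0.219 CPM in the 4 libraries of the C5 arm (3 to 6 counts) and 52.3, 56.4, 83.9 and 11.4 CPM in C5AR1_WT_Mac, C5AR1_WT_Mono, C5AR1_KO_Mac and C5AR1_KO_Mono. Eif2s3y had 29.7 to 36.0 CPM in the C5AR1 arm and at most 0.0364 CPM in the C5 arm. Xist, the transcript of the inactive X chromosome, was present in all 8 libraries at 81.1 to 267 CPM. Kdm5d, also on the Y, had 11.03, 12.2 and 10.9 CPM in the first 3 libraries of the C5AR1 arm and 1 count in C5AR1_KO_Mono, a library of low gene detection. Arm and these genes cannot be separated.

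Fitted alone, with 1 residual degree of freedom, the C5 arm gave 37 genes past the edgeR threshold, 26 lower and 11 higher in the knockout. C5_WT_Mac and C5_KO_Mono, 2 of its 4 libraries and 1 on each side, were of low gene detection, and without them no test is left. Each genotype of an arm is 1 pool, whose macrophage and monocyte libraries stand as its 2 replicates in this fit. The p-values of the single-arm fits therefore do not measure the spread between pools of 1 genotype. Of the 30 interferon-stimulated genes listed, 8 were among the lower ones and 0 among the higher, with Ifit2 at -3.03 (adjusted p 0.000138), Ifit3 at -2.72 (0.00049) and Cxcl10, a chemokine, at -2.77 (0.000754). No enrichment test was run on these calls, and the list also differed between the wild types, with medians of -1.08 and -1.14 in the C5AR1 minus the C5 wild type. Other lower genes were Siglec1, a sialic acid receptor of macrophages, at -2.25 (0.00456), Ccl12 at -4.13 (0.000138), the complement gene Cfb at -2.76 (0.000529), C3ar1, the C3a receptor, at -2.29 (0.00508) and Ly6c2 at -3.72 (0.00132). Higher were Egf at 6.34 (2.81e-08), Thbs1, thrombospondin 1, at 3.13 (0.000754), S100a8 at 2.94 (0.029) and the decoy receptor Il1r2 at 2.51 (0.0299). Mmp9 was higher as well, at 3.40 (0.000143). Of 14 neutrophil markers 3 were among the higher genes and 0 among the lower. The wild types differed here too. In macrophages and monocytes the C5AR1 wild type lay above the C5 wild type by 6.06 and 1.46 (log2) for Mmp9. For S100a8 it was 5.12 and 1.91. C5_WT_Mac had 0.437 CPM of Mmp9 and 0.328 CPM of S100a8. In the C5AR1 arm the knockout differences were -3.00 and 0.88 for Mmp9 and -0.94 and 0.09 for S100a8. A low C5 wild type and a rise in the C5 knockout cannot be told apart here. The C5AR1 arm alone gave 1 gene, Umod, uromodulin of the distal tubule, at -3.07 (0.0259). Whether the arms differ in these genes was not tested.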
